A study of Mus musculus with 16 samples.

How the data were processed

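Total RNA from the whole ovaries of mice aged 1 year was hybridised, after labelling with the dye Cy3, to single-colour Agilent whole mouse genome arrays. There were 16 arrays, 4 in each of 4 groups, and each sample was placed in its group by its title. The groups were a control with one allele of each estrogen receptor (ER), Ex3aERKO (ERα knockout), Ex3bERKO (ERβ knockout) and Ex3abERKO (lacking both). Arrays are named by group and replicate number, as in Ex3aERKO 2. The labels do not say whether the 4 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The 16 arrays lay on 4 slides, scanned in 1 session per slide. Slides 1 and 4 held 1 array of each group, slide 2 held 2 Ex3abERKO arrays and no Ex3bERKO array, and slide 3 held 2 Ex3bERKO arrays and no Ex3abERKO array.

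The spot intensity values were made with Agilent Feature Extraction, per the file headers, which subtracted background and a spatial trend within each array and gave spots not above background a small substitute value. The submitters' processing notes name Feature Extraction 9.5. No normalization between arrays had been applied. The authors' series table held the same intensity values, which equalled the scanner files' processed signal for all 41174 probes, within a tolerance of 0.0001 and after averaging the spots of a probe. Its scale was therefore linear and not centred, with column medians from 149 to 253.

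Each array's processed signal was divided by its 75th percentile over the 43379 non-control spots, values were floored at -8.88 on the log2 scale, and log2 was taken. Spots marked as outliers by Feature Extraction were left out (54 to 106 per array), saturated spots were kept (0 to 7 per array), and the spots of a probe were averaged. A probe was kept when its spots were well above background on at least 4 of the 16 arrays, which held for 36224 probes (30117 on all 16). Where a gene had several kept probes, the one with the highest mean signal represented it. This left 25502 features for testing, 20188 of them with a gene symbol. Probes were named through their accession in a table of RefSeq genes of the assembly GRCm38.p6 (22951), by a current (6571) or older (4589) file symbol, or had none (7063). Coordinates are those of the array files (mm7), counted from 1. No genome sequence of that build was used here, so exons and untranslated regions are not given.

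The model was limma's lmFit and eBayes over all 16 arrays with 1 mean per group, 12 residual degrees of freedom and no covariate. It gave 6 pairwise comparisons and an interaction contrast, (Ex3abERKO minus Ex3aERKO) minus (Ex3bERKO minus control). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 25502 features of a comparison, and a gene was called at an adjusted p under 0.05. Values after ± are standard errors from this model unless marked as SD, and every group has n = 4. Where a gene was not well above background on any array of a group, only a bound is given for pairwise comparisons, written as "at least": the brighter group's mean against the mean, over the dim group's arrays, of the higher of the array's lowest signal among probes well above background and the probe's own signal. Some genes with an exact value were well above background on only part of the arrays of a group compared: Defb8 (3 of 4 control and Ex3bERKO), Slc35f1 (3 of 4 Ex3aERKO), Sox8 (2 of 4 control), Glycam1 (2 of 4 Ex3aERKO) and, in the interaction, Klk1b24 (3 of 4 control), Etos1 (1 of 4 Ex3aERKO, 3 of 4 Ex3bERKO and 2 of 4 Ex3abERKO) and Slc7a10 (1 of 4 Ex3aERKO and 3 of 4 Ex3bERKO). On simulated data for the real genes, with 100 features changed by 1 and 100 by 2 on the log2 scale, the model recovered 33% and 76% of them for Ex3aERKO against control, 44% and 79% for Ex3bERKO against control, 40% and 82% for Ex3abERKO against control, and 6% and 61% for the interaction. It recovered 33% and 76% for Ex3abERKO against Ex3aERKO, 38% and 82% for Ex3abERKO against Ex3bERKO, and 33% and 84% for Ex3aERKO against Ex3bERKO. Between 3 and 11 unchanged features were called per comparison.

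There were 23 gene lists with 346 entries, from textbook knowledge. They covered Sertoli cells, granulosa cells, genes of both supporting cell types, theca and Leydig cells, luteal cells, ovulation, oocytes, estrogen response, cholesterol synthesis, retinoic acid, Wnt signalling, the cell cycle and interferon response, and as markers of other cells macrophages, lymphocytes, endothelium, stroma and matrix, smooth muscle, surface epithelium, oviduct, adipose tissue, erythroid cells and immediate early genes. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 23 lists, with an estimated correlation and fry as alternatives. A list's change is the mean over its measured genes. In simulated data with 2 shifted lists, both were called in each of the 7 comparisons, and 1 of the 21 other lists in 1. The estimated correlation of real lists reached 0.82 (oocytes), so this may not hold for them. A list of 20 liver genes was added after the values had been seen.

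The genes named per comparison were chosen by this rule: Esr1, Esr2, Sox9, Amh, Dmrt1, Foxl2, Cyp19a1, Fshr and Lhcgr; the 6 called genes with the highest and the 6 with the lowest log2 fold change among those with a symbol that is not a clone name, a Gm or LOC number or an accession, and whose arrays did not overlap between the 2 groups; and for each list described, up to 4 called members with the lowest adjusted p. For the interaction, the overlap condition was left out and only Esr1, Esr2 and Sox9 were fixed. The grouping, the model, the lists, this rule and the alternatives listed next were set before the data were examined. Not all genes that the rule selects are printed.

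These alternatives were quantile normalization, normexp background correction with an offset of 50, scaling to the median, no filter or a filter on all 16 arrays, a higher floor, the mean of a gene's probes, slide as a fixed or random block, a replicate block, a variance trend with robust estimation, array weights, only the arrays compared, the series table's values, a 2-fold threshold and leaving out each array. An alternative without the arrays highest in liver (Ex3aERKO 2), oviduct (Ex3abERKO 2) and erythroid genes (control 4) was chosen after seeing the data. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.271 in the comparison of Ex3aERKO with control.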

Results

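The study asked what the estrogen receptors ERα and ERβ do in the change of ovarian granulosa cells toward another cell type in aged ovaries. Granulosa cells surround the oocyte, and Sertoli cells are their counterpart in the testis. RNA from whole ovaries of mice aged 1 year was measured on 16 arrays, 4 each from control, Ex3aERKO (ERα knockout), Ex3bERKO (ERβ knockout) and Ex3abERKO (lacking both) mice. Signal was similar across the arrays, with a 75th percentile between 1211 and 1806 and between 80.4% and 87.6% of the spots well above background. Arrays of a group correlated across probes at r from 0.974 to 0.986 in control, 0.955 to 0.983 in Ex3aERKO, 0.965 to 0.980 in Ex3bERKO and 0.956 to 0.979 in Ex3abERKO. Levels below are log2 signal relative to each array's 75th percentile.

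Esr1, which encodes ERα, was read by a probe at chromosome 10, 5343241 to 5343300 (mm7). Its level in replicates 1 to 4 was -0.32, -0.17, -0.12 and 0.20 in control, -2.18, -2.18, -1.89 and -3.65 in Ex3aERKO, 0.34, -0.57, -1.06 and -0.73 in Ex3bERKO, and -1.86, -1.03, -2.10 and -1.93 in Ex3abERKO. It fell by 2.37 ± 0.37 (5.19-fold, adjusted p = 0.00175) in Ex3aERKO and by 1.63 ± 0.37 (adjusted p = 0.00652) in Ex3abERKO against control, and with slide as a block these values were -2.37 and -1.68. Esr2, which encodes ERβ, was read at chromosome 12, 74079895 to 74079954. Its level was -0.21, 0.35, -0.33 and -0.23 in control, -0.32, -1.07, -1.01 and 1.59 in Ex3aERKO, 0.04, -0.58, 1.00 and 0.85 in Ex3bERKO, and -1.62, -2.52, -1.60 and -2.53 in Ex3abERKO. Esr2 fell by 1.97 ± 0.51 (3.90-fold, adjusted p = 0.0132) in Ex3abERKO, a call lost without the 3 arrays highest in liver, oviduct or erythroid genes (Ex3aERKO 2, Ex3abERKO 2 and control 4, adjusted p = 0.0645), while the difference in Ex3bERKO was 0.43 ± 0.51 (adjusted p = 0.913). The sources used here do not give which part of either gene was removed, so the level of a probe does not check the labels.

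**Figure D1:**
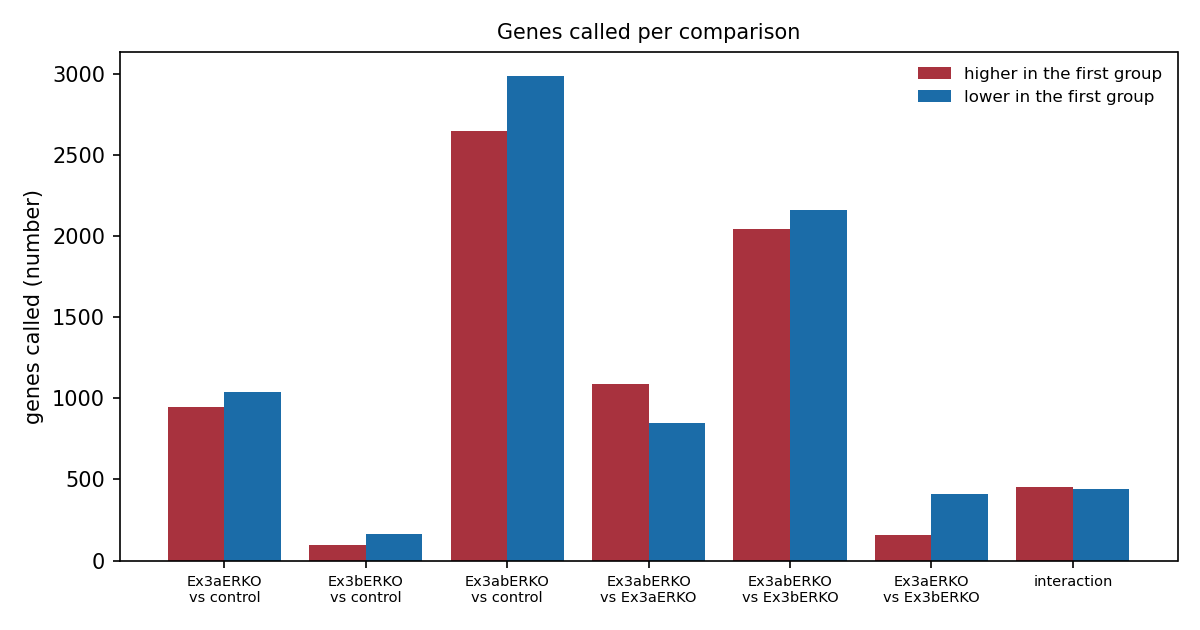
Number of genes called higher (red) and lower (blue) in the first group of each of the 7 comparisons, from 0 upward, at an adjusted p under 0.05.

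The comparison of Ex3aERKO with control gives the ovary without ERα. Insl3, a hormone of Leydig and theca cells, rose by 6.90 ± 1.18 (120-fold, adjusted p = 0.00273). Hsd17b3, the testicular enzyme that makes testosterone, rose by 6.25 ± 0.80 (76.3-fold, adjusted p = 0.000464), and Cyp17a1, which makes androgen precursors, by 2.76 ± 0.38 (6.78-fold, adjusted p = 0.000707). Cyp19a1, the aromatase that turns androgens into estrogens, rose by 3.17 ± 0.60 (9.02-fold, adjusted p = 0.00496). Lcn2, an iron-scavenging lipocalin, rose by 8.48 ± 1.08 (356-fold, adjusted p = 0.000454), and Defb8, a defensin, by 6.88 ± 0.77. Slc35f1, a transporter, fell by 4.82 ± 0.48 (28.2-fold, adjusted p = 9.77e-05) and Mmel1, a peptidase, by 4.59 ± 0.72.

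Of 20 measured Sertoli cell genes, 6 rose, 0 fell and 14 did not pass. Adjusted over the list alone, 9 rose. Rhox5, a homeobox gene of Sertoli cells, rose by 2.70 ± 0.22 (adjusted p = 5.35e-05), Cldn11, which builds tight junctions between Sertoli cells, by 3.85 ± 0.46, and Ptgds, a prostaglandin D synthase, by 6.25 ± 0.99. The list's mean change was 1.09 (camera, adjusted p = 5.47e-06, or 0.136 with an estimated correlation), from 0.74 to 1.54 within the 4 slides. Sox9, the transcription factor that directs Sertoli cell fate, differed by 1.10 ± 0.37 (adjusted p = 0.0917), passing without Ex3aERKO 4 (adjusted p = 0.0169) and with array weights (0.00594). 1 of its 2 other probes differed in the opposite direction and was not called. Dmrt1 was well above background on no array of either group. Among the 19 granulosa cell genes, 2 rose, 0 fell and 17 did not pass, with the same counts when adjusted over the list alone, and the list's mean change was 0.46 (camera, adjusted p = 0.0369, or 0.367 with an estimated correlation). That call was lost without control 1, 3, Ex3aERKO 1 or 4 (adjusted p = 0.0626 to 0.242), with array weights (0.0552), the filter on all 16 arrays (0.0502), only the groups compared (0.0582) or fry (0.212), and the within-slide values ran from 0.03 to 1.37. Foxl2, which maintains granulosa cell identity, differed by -0.04 ± 0.15 (adjusted p = 0.944). Fshr, the receptor for follicle-stimulating hormone, differed by 1.26 ± 0.38 (adjusted p = 0.0583), passing without control 2, Ex3aERKO 2 or 3 (0.0302 to 0.0438), with slide as a fixed (0.0194) or random (0.0297) block, with array weights (0.0303), trend and robust (0.0406), normexp (0.0435), median scaling (0.0497) or the filter on all 16 arrays (0.0472). Lhcgr, the receptor for luteinizing hormone, differed by -0.97 ± 0.57 (adjusted p = 0.378).

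Amh, anti-Müllerian hormone, which both supporting cell types make, fell by 1.71 ± 0.45 (3.27-fold, adjusted p = 0.0298). Its call was lost without control 2, 3, 4, Ex3aERKO 3 or 4 (adjusted p = 0.0545 to 0.0948), and without those 3 arrays (0.0748). Of the 14 genes of both supporting cell types, Kitl, which encodes the ligand of the receptor Kit, rose by 1.27 ± 0.29 and Amhr2, the receptor for Amh, by 0.96 ± 0.21. Amh was the third called member, and 3 rose and 1 fell adjusted over the list alone (mean change 0.23; camera, adjusted p = 0.0408, or 0.308 with an estimated correlation), a call lost without control 1, 3, 4, Ex3aERKO 1, 3 or Ex3bERKO 2 (0.0518 to 0.0992).

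Other ovarian lists moved as well. Of 23 oocyte genes, 0 rose, 19 fell and 4 did not pass, and 21 fell adjusted over the list alone (mean change -2.49; camera, adjusted p = 8.89e-19, or 0.136 with an estimated correlation). Examples were Zp3, a protein of the egg coat, which fell by 3.13 ± 0.46, and Bmp15, an oocyte growth factor, which fell by 3.04 ± 0.47. Of 12 luteal genes, 6 fell, 0 rose and 6 did not pass, and 8 fell adjusted over the list alone (mean change -1.74; camera, adjusted p = 6.64e-08, or 0.136 with an estimated correlation). Rgcc fell by 3.21 ± 0.34 and Hsd17b7, an enzyme of steroid and cholesterol synthesis, by 3.30 ± 0.45. Of 21 cholesterol synthesis genes, 6 fell, 0 rose and 15 did not pass, and 12 fell adjusted over the list alone (mean change -0.98; camera, adjusted p = 1.24e-08, or 0.219 with an estimated correlation). The within-slide values of that list were -1.15, -1.53, 0.05 and -1.30. The 15 theca and Leydig genes went both ways: 4 rose, 6 fell and 5 did not pass, with 4 and 8 adjusted over the list alone, a mean of 0.36, a median of -0.78 and no call (camera toward lower values, adjusted p = 0.278). Those that fell included Cyp11a1, which makes pregnenolone from cholesterol (-1.94 ± 0.32), and Srd5a1, a steroid 5α-reductase (-2.77 ± 0.36). Of 14 ovulation genes, 4 rose, 0 fell and 10 did not pass, with 4 and 1 adjusted over the list alone (mean change 0.61; camera, adjusted p = 0.0369, or 0.308 with an estimated correlation), a call lost without control 1, 3, Ex3aERKO 1 or 2 (0.0589 to 0.0788). Of 13 estrogen response genes, 2 rose, 1 fell and 10 did not pass, with 6 and 1 adjusted over the list alone (mean change 1.31; camera, adjusted p = 0.000505, or 0.0452 with an estimated correlation). Lcn2 and C3, a complement protein (3.41 ± 0.53), rose and Ramp3, a receptor-modifying protein, fell by 1.30 ± 0.19. Among markers of other cells, 4 of 20 macrophage genes rose, 0 fell and 16 did not pass, and 15 rose adjusted over the list alone (mean change 1.09; camera, adjusted p = 1.20e-10, or 0.136 with an estimated correlation). Of 13 endothelial genes, 8 fell, 0 rose and 5 did not pass, with 10 lower and 1 higher adjusted over the list alone (mean change -0.71; camera, adjusted p = 3.31e-07, or 0.136 with an estimated correlation).

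In all, 1987 genes were called, 947 higher and 1040 lower, of which 1391 differed at least 2-fold. The count was 2215 with slide as a block and 5594 with array weights. All 64 named genes called in this comparison went the same way on every slide, which the rule for naming genes favours here and in the comparisons below. The number called was 1307, 1174 and 1273 without control 1, 3 and 4, 1157 and 1221 without Ex3aERKO 2 and 3, and 551 without those 3 arrays, where Cyp19a1 (adjusted p = 0.0507) and Amhr2 (0.0762) no longer passed.

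**Figure D2:**
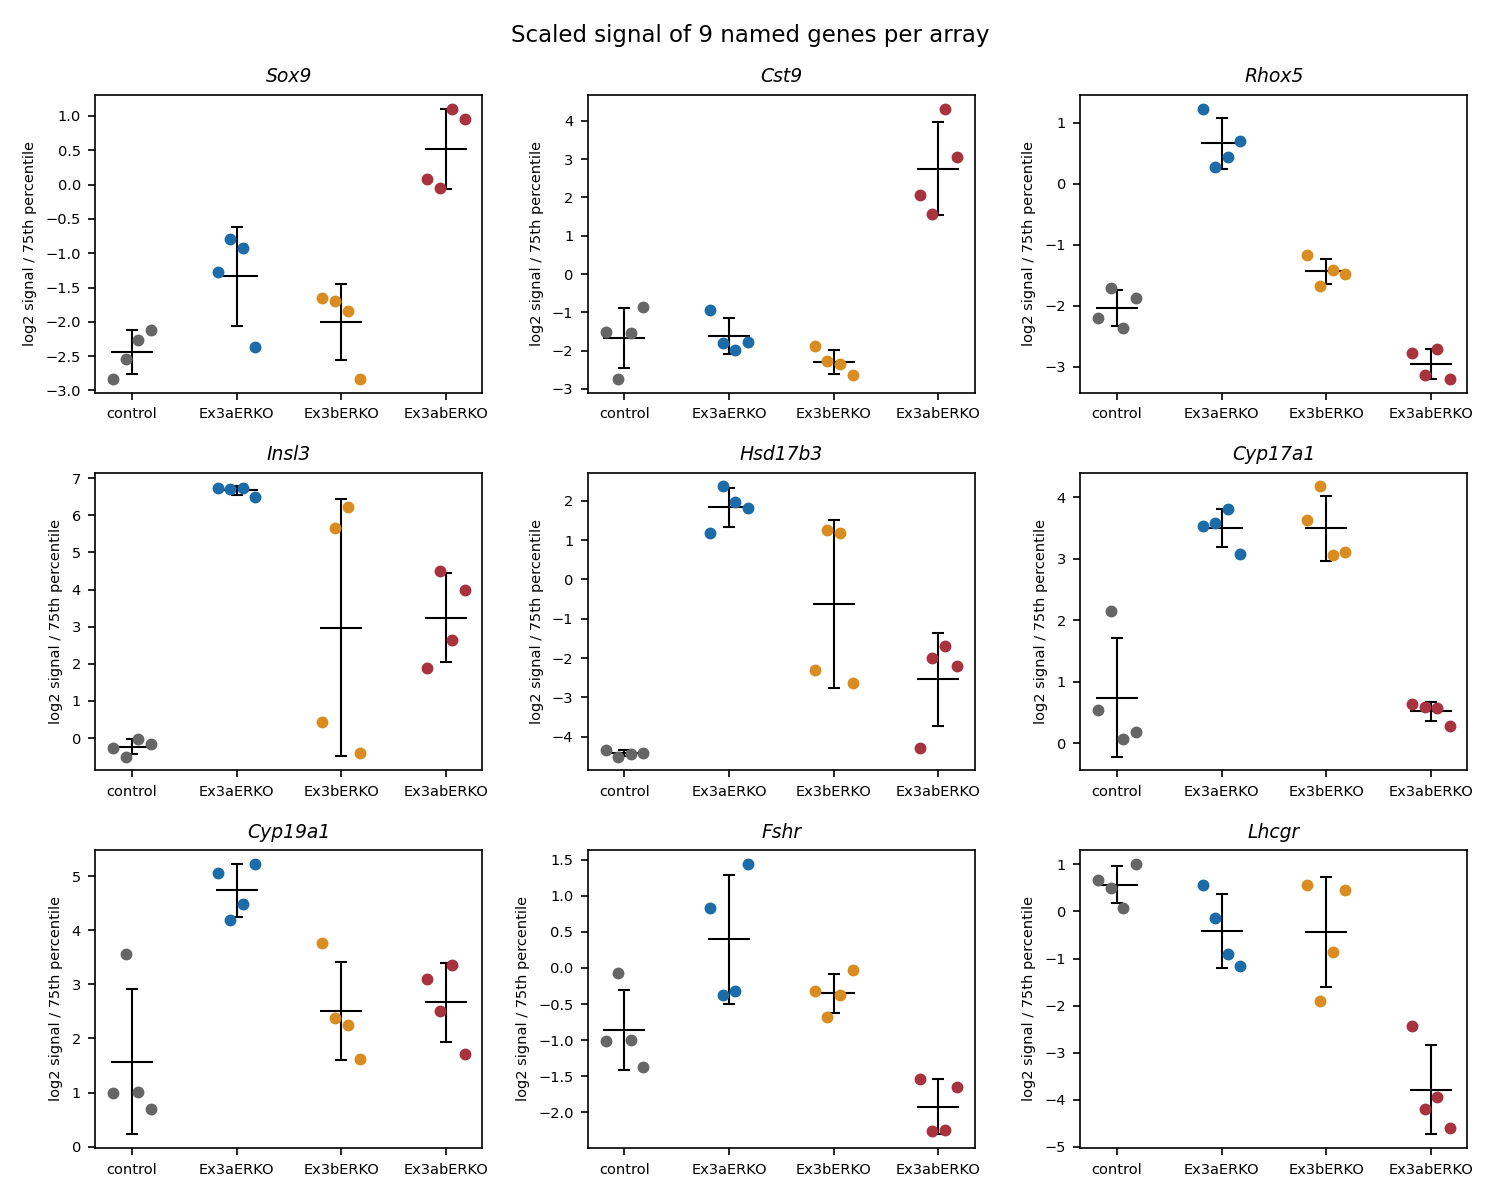
Level of 9 named genes on each array (log2 signal relative to the array's 75th percentile), 4 points per group, with mean (bar) and SD. Sox9 lies between -0.05 and 1.09 on the 4 Ex3abERKO arrays and between -2.84 and -2.12 on the 4 control arrays.

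The comparison of Ex3bERKO with control gives the ovary without ERβ, and fewer genes passed. Plin4 and Plin5, proteins that coat lipid droplets, fell by 5.43 ± 0.38 (43.0-fold, adjusted p = 1.05e-05) and 4.75 ± 0.55 (26.8-fold, adjusted p = 0.00106). Mmel1 fell by 5.80 ± 0.72 (adjusted p = 0.00142). Eppin, a protease inhibitor of the male tract, rose by 3.47 ± 0.40 (11.1-fold, adjusted p = 0.00106), and Cyp17a1 by 2.76 ± 0.38 (6.75-fold, adjusted p = 0.00298). Star, which carries cholesterol into mitochondria, fell by 2.63 ± 0.44 (adjusted p = 0.00960).

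Of 20 Sertoli cell genes, 2 rose, 0 fell and 18 did not pass, and 4 rose adjusted over the list alone. The list's mean change was 0.72 (camera, adjusted p = 1.18e-05, or 0.139 with an estimated correlation). It was 0.88, 0.56 and 0.93 within the 3 slides that held both groups, with an adjusted p of 2.31e-05 with slide as a block. The called members were Aard, which rose by 2.37 ± 0.46 (adjusted p = 0.0223), and Cldn11, which rose by 2.07 ± 0.46 (adjusted p = 0.0456). Aard was not called without control 1, 3, 4, Ex3bERKO 1 or 3 (adjusted p = 0.0674 to 0.0801), nor with slide as a block (0.0520), only the groups compared (0.0812) or without those 3 arrays (0.0848). The call of Cldn11 was kept without Ex3aERKO 4, Ex3bERKO 4 or Ex3abERKO 3 and lost without any other array (0.0560 to 0.147), and also lost with median scaling (0.0604), no filter on dim probes (0.0558), only the groups compared (0.129) or without those 3 arrays (0.179). Sox9 differed by 0.43 ± 0.37 (adjusted p = 0.841) and Amh by 0.31 ± 0.45 (adjusted p = 0.947). Among the 19 granulosa cell genes none passed, over all genes or adjusted over the list alone (0 and 0), and the list was not called (mean change -0.17; camera, adjusted p = 0.585). Foxl2 differed by -0.10 ± 0.15, Cyp19a1 by 0.94 ± 0.60, Fshr by 0.51 ± 0.38 and Lhcgr by -1.01 ± 0.57, with adjusted p values of 0.950, 0.721, 0.794 and 0.648. Dmrt1 was well above background on no array of either group.

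Of 12 luteal genes, 2 fell, Star and Hsd17b7 (-3.88 ± 0.45, adjusted p = 0.00106), and 10 did not pass. Adjusted over the list alone, 10 fell, and the list's mean change was -1.85 (camera, adjusted p = 1.47e-14, or 0.0433 with an estimated correlation). Of 21 cholesterol synthesis genes, 5 fell, 0 rose and 16 did not pass, and 14 fell adjusted over the list alone (mean change -1.07; camera, adjusted p = 1.96e-18, or 0.116 with an estimated correlation). Mvd, a mevalonate pathway enzyme, fell by 2.08 ± 0.35 (adjusted p = 0.00903). None of 23 oocyte genes passed, nor any adjusted over the list alone (0 and 0), while the list's mean change was 0.74 (camera, adjusted p = 1.81e-05, or 0.564 with an estimated correlation). Of 15 theca and Leydig genes, 2 rose, 1 fell and 12 did not pass, with 3 and 6 adjusted over the list alone, and the list had a mean of 0.15, a median of -0.54 and no call (camera toward lower values, adjusted p = 0.280). None of the 20 macrophage genes was called, nor any adjusted over the list alone (0 and 0), with a mean change of 0.56 (camera, adjusted p = 9.71e-06, or 0.385 with an estimated correlation).

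In all, 258 genes were called, 96 higher and 162 lower, 226 of them at least 2-fold, and all 22 named genes called went the same way on every slide that held both groups. The count was 181 with slide as a block, 862 with array weights, 126, 110 and 119 without control 1, 3 and 4, 119 without Ex3bERKO 3, and 66 without those 3 arrays, where Star (adjusted p = 0.0686) and Mvd (0.0913) no longer passed. In a model with only the 8 arrays compared it was 89, and Cyp17a1 (adjusted p = 0.0683), Star (0.1003), Mvd (0.0689) and Mmel1 (0.0517) were not called.

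The comparison of Ex3abERKO with control gives the ovary without either receptor, and more genes were called in it than in the other comparisons. Sox9 rose by 2.96 ± 0.37 (7.79-fold, adjusted p = 0.000152), with within-slide differences of 3.93, 2.14 and 3.22. Dmrt1, which maintains male gonad identity, was at least 2.51-fold higher (adjusted p = 0.000394), being well above background on all 4 Ex3abERKO arrays and on no array of the other groups. Of 20 Sertoli cell genes, 10 rose, 2 fell and 8 did not pass, with 13 and 2 adjusted over the list alone. Defb36, a Sertoli cell defensin, rose by 4.64 ± 0.43 (24.9-fold, adjusted p = 1.93e-05), Cst9, a cystatin of fetal Sertoli cells, by 4.42 ± 0.51 (21.4-fold, adjusted p = 8.79e-05), Cldn11 by 4.66 ± 0.46 and Sox8, a relative of Sox9, by 2.89 ± 0.32. The list's mean change was 1.64 (camera, adjusted p = 1.84e-06, or 0.106 with an estimated correlation), from 1.23 to 2.24 within slides and with an adjusted p of 6.23e-06 with slide as a block.

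Among the 19 granulosa cell genes, 8 fell, 2 rose and 9 did not pass, with 9 and 2 adjusted over the list alone. Nr5a2, a nuclear receptor required for ovulation, fell by 3.11 ± 0.37 (8.66-fold, adjusted p = 0.000102) and Fst, follistatin, by 2.48 ± 0.46 (5.58-fold, adjusted p = 0.00157), while Rspo1, a Wnt activator, rose by 2.00 ± 0.27. The list's mean change was -0.84 (camera, adjusted p = 0.0219, or 0.305 with an estimated correlation), from -0.85 to -0.55 within slides. That call was lost without control 2, Ex3abERKO 3 or 4 (adjusted p = 0.0598 to 0.0833) or with array weights (0.0746). Lhcgr fell by 4.36 ± 0.57 (20.5-fold, adjusted p = 0.000187) and Amh by 1.90 ± 0.45 (3.72-fold, adjusted p = 0.00748). Foxl2 differed by -0.22 ± 0.15 (adjusted p = 0.346). Fshr differed by -1.06 ± 0.38 (adjusted p = 0.0612), passing without Ex3aERKO 2 (0.0497) or Ex3aERKO 4 (0.0277), with trend and robust (0.0479) and with array weights (0.0234), and Cyp19a1 by 1.10 ± 0.60 (adjusted p = 0.216), passing without control 2 (0.0187). Of 14 genes of both supporting cell types, 3 rose, 5 fell and 6 did not pass, with 4 and 7 adjusted over the list alone and no call (mean change -0.37; camera, adjusted p = 0.594). Nr5a1, which drives steroid-making genes, fell by 2.23 ± 0.25, Gata4, a gonadal transcription factor, fell by 1.22 ± 0.26, and Wt1, a transcription factor of supporting cells, rose by 1.57 ± 0.32.

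Of 15 theca and Leydig genes, 8 fell, 3 rose (Insl3, Hsd11b1 and Por) and 4 did not pass, with 9 and 4 adjusted over the list alone (mean change -1.08; camera, adjusted p = 0.00178, or 0.0854 with an estimated correlation). Srd5a1 fell by 4.39 ± 0.36 (20.9-fold, adjusted p = 7.09e-06) and Cyp11a1 by 3.48 ± 0.32 (11.2-fold, adjusted p = 1.83e-05). Of 12 luteal genes, 8 fell and 4 did not pass, and 8 fell adjusted over the list alone (mean change -2.22; camera, adjusted p = 4.95e-07, or 0.106 with an estimated correlation). Scarb1, a lipoprotein receptor, fell by 2.68 ± 0.32 and Prlr, the prolactin receptor, by 2.59 ± 0.31. Of 21 cholesterol synthesis genes, 20 fell and 1 did not pass, and 20 fell adjusted over the list alone (mean change -1.72; camera, adjusted p = 6.89e-13, or 0.125 with an estimated correlation). Hmgcs1 fell by 2.56 ± 0.32. Of 23 oocyte genes, 16 fell and 7 did not pass, and 18 fell adjusted over the list alone (mean change -1.78; camera, adjusted p = 1.35e-07, or 0.305 with an estimated correlation). Of 20 cell cycle genes, 14 fell and 6 did not pass, and 17 fell adjusted over the list alone (mean change -1.02; camera, adjusted p = 1.11e-05, or 0.305 with an estimated correlation). Of 13 estrogen response genes, 5 rose, 4 fell and 4 did not pass, also adjusted over the list alone (5 and 4), with no call for the list (mean change 0.81; camera, adjusted p = 0.104).

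All 20 macrophage genes rose, and 20 rose adjusted over the list alone (mean change 1.84; camera, adjusted p = 2.24e-14, or 0.106 with an estimated correlation). Examples were Trem2, a receptor of lipid-handling macrophages (2.72 ± 0.37), and Cd68, a lysosomal protein (2.70 ± 0.38). Of 16 lymphocyte genes, 12 rose and 4 did not pass, and 13 rose adjusted over the list alone (mean change 2.00; camera, adjusted p = 8.63e-09, or 0.106 with an estimated correlation). Jchain, which joins secreted antibodies, rose by 5.97 ± 0.88 (62.8-fold) and Ms4a1, the B cell antigen CD20, by 3.89 ± 0.63. Of 13 endothelial genes, 6 fell, 1 rose and 6 did not pass, with 8 and 1 adjusted over the list alone (mean change -0.41; camera, adjusted p = 0.0148, or 0.305 with an estimated correlation), a call lost without control 4 (0.0501) or Ex3abERKO 3 (0.0802). Outside the lists, Lpar3, a receptor for lysophosphatidic acid, was at least 68.7-fold higher (adjusted p = 3.60e-07) and Cidea, a lipid droplet protein, rose by 6.41 ± 0.58.

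In all, 5642 genes were called, 2652 higher and 2990 lower, 3218 of them at least 2-fold, and the count was 5446 with slide as a block and 9210 with array weights. The median of all log2 fold changes was -0.11, and -0.06 when arrays were scaled to their median. All 94 named genes called went the same way on every slide that held both groups, and without those 3 arrays 3336 genes were called.

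**Figure D3:**
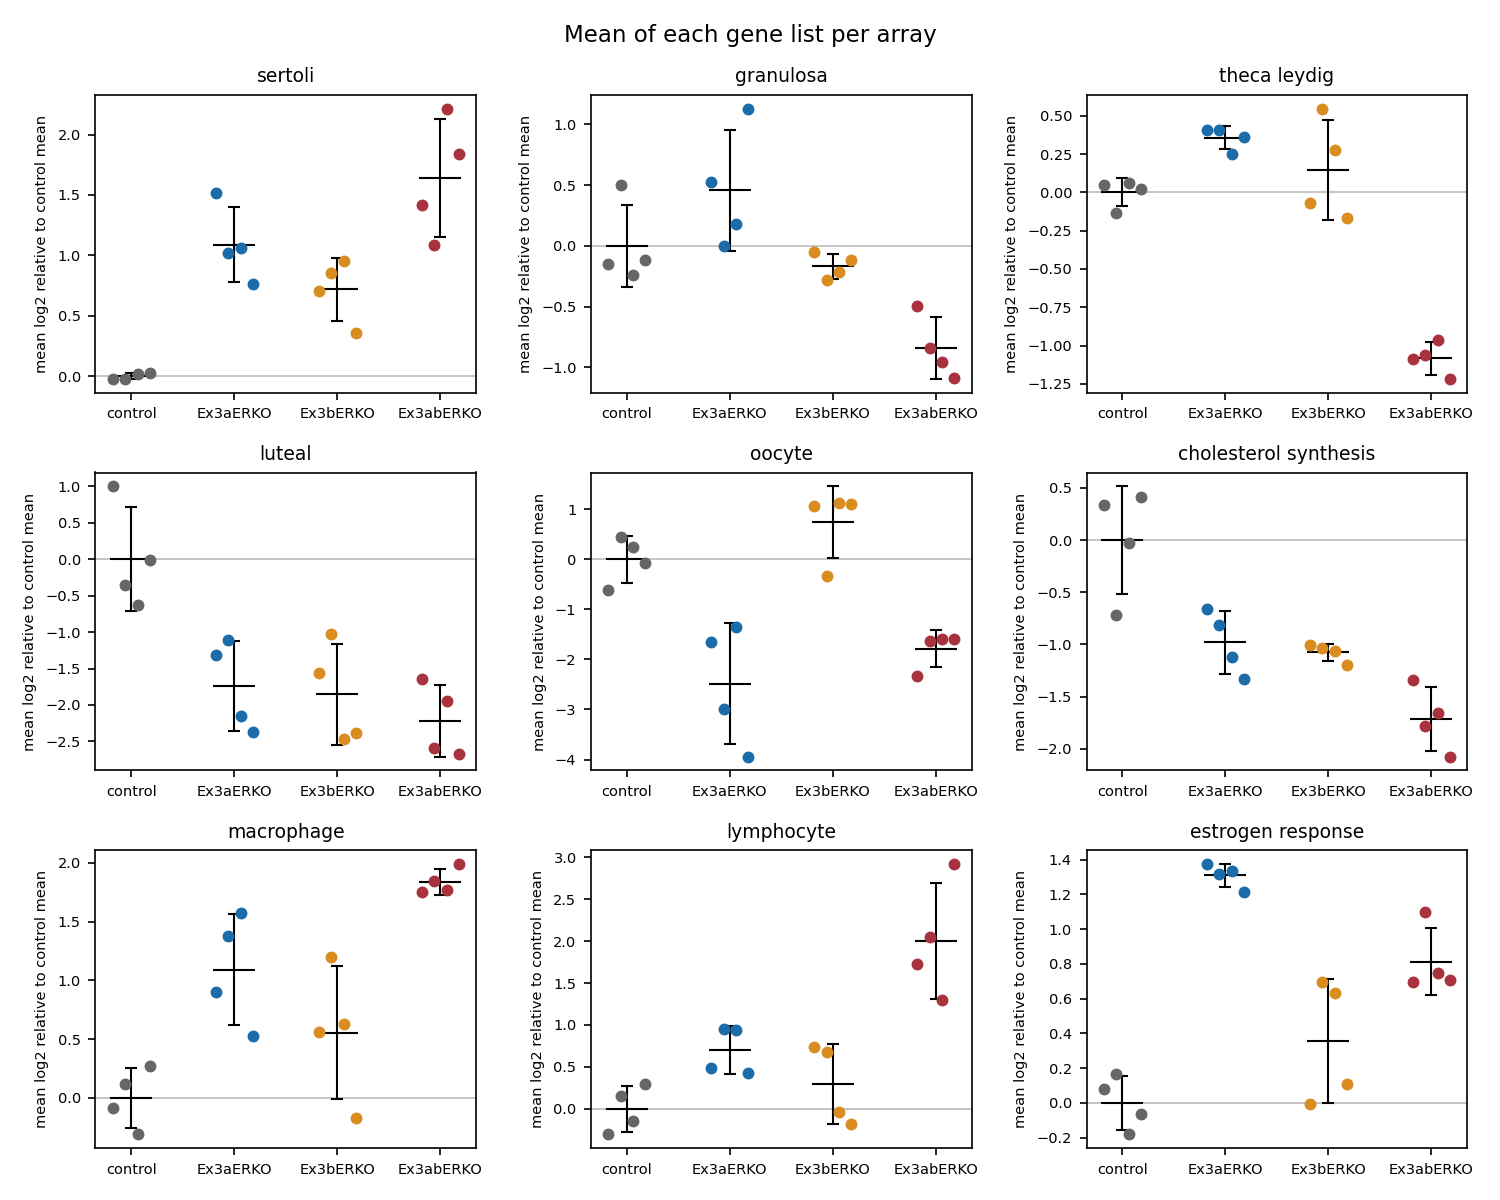
Mean log2 level of 9 gene lists on each array, relative to the control mean (horizontal line at 0), 4 points per group, with mean (bar) and SD. The macrophage list lies above 0 on all Ex3abERKO arrays, with a mean of 1.84.

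Ex3abERKO against Ex3aERKO asks what the loss of ERβ adds where ERα is missing. Sox9 rose by 1.86 ± 0.37 (3.63-fold, adjusted p = 0.00898), with within-slide differences of 1.89, 0.93 and 3.33. Dmrt1 was at least 3.05-fold higher (adjusted p = 0.000943). Cst9 rose by 4.38 ± 0.51 (20.8-fold, adjusted p = 0.000415) and Defb36 by 3.48 ± 0.43, but Rhox5, also of Sertoli cells, fell by 3.62 ± 0.22 (12.3-fold, adjusted p = 1.97e-06). Cyp17a1 fell by 2.98 ± 0.38 (7.91-fold, adjusted p = 0.000715) and Hsd17b3 by 4.38 ± 0.80 (20.8-fold, adjusted p = 0.00541). So did Fshr (-2.32 ± 0.38, adjusted p = 0.00296) and Lhcgr (-3.38 ± 0.57, adjusted p = 0.00345). Glycam1, a mucin-like ligand of lymphocyte homing, rose by 5.41 ± 0.43 (42.5-fold, adjusted p = 1.46e-05).

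Of 20 Sertoli cell genes, 6 rose, 2 fell and 12 did not pass, with 7 and 4 adjusted over the list alone (mean change 0.55; camera, adjusted p = 0.0164, or 0.403 with an estimated correlation). The call was lost without Ex3aERKO 4 (adjusted p = 0.0530) or Ex3abERKO 3 (0.0604), with array weights (0.166), the filter on all 16 arrays (0.2005) or fry (0.0842), and the within-slide values were 1.19, 0.20 and 1.08, with an adjusted p of 0.0437 with slide as a block. Of 19 granulosa cell genes, 10 fell, 0 rose and 9 did not pass, with 12 and 2 adjusted over the list alone (mean change -1.30; camera, adjusted p = 4.09e-06, or 0.199 with an estimated correlation). They included Nr5a2 (-2.63 ± 0.37) and Inhba, a subunit of activin (-2.99 ± 0.43). Of 14 genes of both supporting cell types, 4 fell, 0 rose and 10 did not pass, and 4 fell adjusted over the list alone (mean change -0.60; camera, adjusted p = 0.00727, or 0.313 with an estimated correlation). Of 15 theca and Leydig genes, 8 fell, 1 rose and 6 did not pass, with 11 and 1 adjusted over the list alone (mean change -1.44; camera, adjusted p = 1.98e-06, or 0.00275 with an estimated correlation). Lymphocyte genes were higher, 5 of 16 called and 6 adjusted over the list alone (mean change 1.30; camera, adjusted p = 2.57e-06, or 0.313 with an estimated correlation). Amh (-0.19 ± 0.45), Foxl2 (-0.18 ± 0.15) and Esr1 (0.74 ± 0.37) were not called, with adjusted p values of 0.872, 0.547 and 0.268.

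Esr2 fell by 1.87 ± 0.51 (adjusted p = 0.0390), a call lost without control 1, 3, Ex3aERKO 1, 4, Ex3abERKO 2 or 4 (0.0512 to 0.0976), with slide as a block (0.0646), with only the groups compared (0.136) and without those 3 arrays (0.0928). Cyp19a1 fell by 2.07 ± 0.60 (adjusted p = 0.0488), a call kept without control 2, Ex3bERKO 1, Ex3bERKO 4 or Ex3abERKO 3 and lost without any other array (0.0506 to 0.131), with slide as a block (0.0866), with median scaling (0.0567), with no filter on dim probes (0.0574) and without those 3 arrays (0.116). In all, 1938 genes were called, 1090 higher and 848 lower, 1264 of them at least 2-fold, and 1943 with slide as a block, and 62 of 63 named genes called went the same way on every slide, all but Cidec. The count was 1133 and 1128 without Ex3aERKO 1 and 4 and 862 without those 3 arrays. In a model with only the 8 arrays compared it was 613, and Sox9 was not called (adjusted p = 0.0547).

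Ex3abERKO against Ex3bERKO asks what the loss of ERα adds where ERβ is missing. Sox9 rose by 2.53 ± 0.37 (5.76-fold, adjusted p = 0.000783), with 2.79 and 2.80 on the 2 slides that held both groups. Dmrt1 was at least 3.07-fold higher (adjusted p = 0.00132), Cst9 rose by 5.04 ± 0.51 (32.9-fold, adjusted p = 6.80e-05) and Rhox5 fell by 1.52 ± 0.22 (adjusted p = 0.000652). Amh fell by 2.20 ± 0.45 (4.61-fold, adjusted p = 0.00467), Lhcgr by 3.35 ± 0.57 (10.2-fold, adjusted p = 0.00168), Cyp17a1 by 2.98 ± 0.38 (7.88-fold, adjusted p = 0.000379) and Srd5a1 by 3.75 ± 0.36 (13.4-fold, adjusted p = 3.71e-05). Bpifb5 fell by 6.45 ± 0.36 (87.7-fold, adjusted p = 6.00e-07).

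Of 20 Sertoli cell genes, 8 rose, 2 fell and 10 did not pass, with 8 and 4 adjusted over the list alone (mean change 0.92; camera, adjusted p = 0.00320, or 0.305 with an estimated correlation), and the within-slide values were 1.36 and 0.89. Among the 19 granulosa cell genes, 8 fell, 1 rose and 10 did not pass, with 9 and 1 adjusted over the list alone (mean change -0.68; camera, adjusted p = 0.0258, or 0.305 with an estimated correlation). That call was lost without Ex3abERKO 3 (adjusted p = 0.0840) or Ex3abERKO 4 (0.0625), and the within-slide values were -0.67 and -0.87. Of 15 theca and Leydig genes, 8 fell, 2 rose and 5 did not pass, with 11 and 2 adjusted over the list alone (mean change -1.23; camera, adjusted p = 0.00018, or 0.0202 with an estimated correlation). Of 23 oocyte genes, 19 fell and 4 did not pass, and 22 fell adjusted over the list alone (mean change -2.53; camera, adjusted p = 6.85e-14, or 0.305 with an estimated correlation). Of 20 macrophage genes, 14 rose and 6 did not pass, and 18 rose adjusted over the list alone (mean change 1.28; camera, adjusted p = 8.82e-11, or 0.305 with an estimated correlation). Foxl2 (-0.12 ± 0.15) and Cyp19a1 (0.17 ± 0.60) were not called, with adjusted p values of 0.654 and 0.890. Esr2 fell by 2.40 ± 0.51 (adjusted p = 0.00636).

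Esr1 fell by 1.23 ± 0.37 (adjusted p = 0.0376), a call lost without Ex3bERKO 1, 2, 4, Ex3abERKO 1, 3 or 4 (0.0573 to 0.115), with median scaling (0.0545), with array weights (0.0681) and with only the groups compared (0.0589). Fshr fell by 1.57 ± 0.38 (adjusted p = 0.0130), a call lost with slide as a block (0.0607). In all, 4205 genes were called, 2046 higher and 2159 lower, 2496 of them at least 2-fold, and the median of all log2 fold changes was -0.10 (-0.05 with median scaling). Of 77 named genes called, 76 went the same way on both slides, all but Atf3. The count was 2191 with slide as a block, 6572 with array weights, 2488 with only the groups compared, 2433 without Ex3bERKO 4 and 2512 without those 3 arrays.

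Ex3aERKO against Ex3bERKO compares the single knockouts directly. Oocyte genes were lower in Ex3aERKO: 21 of 23 fell, 2 did not pass, and 23 fell adjusted over the list alone (mean change -3.23; camera, adjusted p = 1.31e-38, or 0.0664 with an estimated correlation), from -5.07 to -2.66 within slides. Zp3 fell by 3.84 ± 0.46 (14.3-fold, adjusted p = 0.000843). Defb8 rose by 6.75 ± 0.77 (108-fold, adjusted p = 0.000716), and Rhox5 rose by 2.10 ± 0.22 (4.27-fold, adjusted p = 0.000577). Srd5a1 fell by 2.13 ± 0.36. Esr1 fell by 1.97 ± 0.37 (3.92-fold, adjusted p = 0.0107), a call lost with the mean of its probes (adjusted p = 0.0534).

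Of 19 granulosa cell genes, 1 rose, 0 fell and 18 did not pass, with 4 and 1 adjusted over the list alone (mean change 0.63; camera, adjusted p = 0.00273, or 0.336 with an estimated correlation and 0.259 with fry). The Sertoli cell list, with 1 of 20 genes higher and 4 adjusted over the list alone, was not called (mean change 0.37; camera, adjusted p = 0.0571), but passed with slide as a block (adjusted p = 0.0442) and without Ex3aERKO 4, Ex3bERKO 1 or 3 (0.0101 to 0.0438). Estrogen response genes were shifted upward, with 1 of 13 called and 4 higher and 1 lower adjusted over the list alone (mean change 0.95; camera, adjusted p = 0.000394, or 0.0332 with an estimated correlation). Sox9 (0.67 ± 0.37), Foxl2 (0.06 ± 0.15), Fshr (0.75 ± 0.38), Lhcgr (0.03 ± 0.57) and Esr2 (-0.53 ± 0.51) were not called, with adjusted p values of 0.527, 0.939, 0.454, 0.991 and 0.789. Cyp19a1 differed by 2.24 ± 0.60 (adjusted p = 0.0736), passing without control 2 (0.0154) or Ex3bERKO 1 (0.0490), with slide as a random block (0.0415), with trend and robust (0.0478) and with array weights (0.0375). Amh fell by 2.02 ± 0.45 (adjusted p = 0.0280), a call lost without Ex3aERKO 1, 3, 4, Ex3bERKO 1, 3 or 4 (0.0511 to 0.112), with slide as a block (0.0583), with only the groups compared (0.172) and without those 3 arrays (0.0621).

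In all, 569 genes were called, 159 higher and 410 lower, and 493 with slide as a block, and 28 of 29 named genes called went the same way on every slide, all but Amh (0.24 on slide 1). The count was 1612 with array weights, 350 without Ex3aERKO 2, 315, 875 and 281 without Ex3bERKO 1, 2 and 4, 237 without those 3 arrays and 117 in a model with only the 8 arrays compared, where Esr1 (adjusted p = 0.106) and Srd5a1 (0.0645) did not pass.

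The interaction asks whether losing ERα had another effect without ERβ (log2 scale, higher meaning a positive value). Cyp17a1 rose in each single knockout and was lower in the double knockout than in either, with an interaction of -5.74 ± 0.54 (adjusted p = 0.000216), and Hsd17b3 had one of -8.17 ± 1.14 (adjusted p = 0.00187). Rhox5 (-4.22 ± 0.31, adjusted p = 2.75e-05) and Cst9 (4.997 ± 0.72, adjusted p = 0.00218), both Sertoli cell genes, went opposite ways. Fshr had an interaction of -2.83 ± 0.54 (adjusted p = 0.0111) and Nr5a1 of -1.75 ± 0.35 (adjusted p = 0.0155). Sox9 did not pass (1.42 ± 0.53, adjusted p = 0.181), nor did Esr1 (1.15 ± 0.53, adjusted p = 0.301) or Esr2 (-2.30 ± 0.72, adjusted p = 0.107), Esr2 passing with array weights (adjusted p = 0.0281). Of 20 Sertoli cell genes, 4 were higher, 3 lower and 13 not called, with 5 and 4 adjusted over the list alone and no call for the list (mean -0.17; camera, adjusted p = 0.792). Among the 19 granulosa cell genes, 3 were lower, 0 higher and 16 not called, with 8 and 1 adjusted over the list alone (mean -1.13; camera, adjusted p = 0.000314, or 0.317 with an estimated correlation, and 0.000738 with slide as a block). The theca and Leydig list had 3 of 15 genes lower, with 3 lower and 1 higher adjusted over the list alone (mean -1.59; camera, adjusted p = 0.00341, or 0.112 with an estimated correlation, and 0.00164 with slide as a block).

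In all, 896 genes were called in the interaction, 454 higher and 442 lower, and 648 with slide as a block. The count was 1924 with array weights, 584, 569 and 512 without control 1, 3 and 4, 569 without Ex3aERKO 1, 538 without Ex3bERKO 3, 1363 without Ex3abERKO 3 and 278 without those 3 arrays.

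The 3 comparisons with control share the control arrays, which by itself makes their fold changes move together. Ex3aERKO and Ex3abERKO had 638 genes called higher and 703 called lower in both, and 12 called in opposite directions, where independent lists would share 98.5 and 122 and simulated unchanged groups shared 0. Across genes, which are not independent replicates, their fold changes correlated at r = 0.669 with a covariance of 0.421, against 0.501 and 0.0695 in simulated unchanged groups, a difference in covariance of 0.352. With the controls split into sets of 2 arrays, the covariance was 0.335 to 0.390, r was 0.474 to 0.587, and 175 to 257 genes were higher and 170 to 256 lower in both. For Ex3aERKO and Ex3bERKO, 83 genes were higher and 133 lower in both and 1 was opposite, where independent lists would share 3.56 and 6.61, and r was 0.577 with a covariance of 0.199 (simulated 0.5004 and 0.0692, difference in covariance 0.130). Split controls gave r from 0.277 to 0.488, a covariance of 0.121 to 0.175, 6 to 31 genes higher and 25 to 63 lower in both. For Ex3bERKO and Ex3abERKO, 64 genes were higher, 125 lower and 4 opposite, where independent lists would share 9.98 and 19.0, and r was 0.458 with a covariance of 0.203 (simulated 0.5005 and 0.0695, difference in covariance 0.133). Split controls gave r from 0.208 to 0.440, a covariance of 0.116 to 0.195, 5 to 27 genes higher and 22 to 83 lower in both.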

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

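The tests of liver RNA, slide, labels, exchanged samples, blood and cell share in this part were chosen after the results were seen, and chance alone sets about 1 in 20 groups of 4 arrays apart.

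Array Ex3aERKO 2 was high in transcripts of liver. Of 18 measured liver genes, 14 lay over 2 log2 units above the highest other array, where 15 were set as needed for liver RNA carried into the sample. Alb exceeded the next array by 10.2, Apoa2 by 9.82 and Mup1 by 9.75. The 4 others, Apoa1, Ahsg, Trf and Hp, were brighter elsewhere (highest 0.08 to 3.91) than the 14 (-5.64 to -1.29). The missed limit is thus no evidence against liver RNA. A fault of the whole slide is argued against, because the highest liver mean among the other arrays of that slide was -3.87, inside the range of -5.02 to -3.18 of the arrays on other slides. No biological explanation was tested.

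Genes higher in Ex3aERKO than in control were also high on Ex3bERKO 2 and 3, which scored 0.648 and 0.514 between 0 (control mean) and 1 (Ex3aERKO mean), against 0.286 and 0.179 for Ex3bERKO 1 and 4 and 0.748 to 1.05 for the Ex3aERKO arrays. Slide is argued against, since the controls of the same slides differed by -0.14 over 298 genes where the Ex3bERKO arrays differed by 1.23, which is -11.1% of that gap. Ex3aERKO samples carrying the Ex3bERKO name cannot be told apart from a shared effect of the knockouts by 3 tests: the scores fall short of the Ex3aERKO range by less than that range, and of the genes that part Ex3aERKO from control 37.6% to 43.5% lay nearer to the control mean on Ex3bERKO 2 and 3, against 3.75% to 11.1% on Ex3aERKO 1, 2 or 3 left out in turn, but 36.1% and 52.2% against 42.1% with Ex3aERKO 4 left out. Over 21258 genes, both arrays lay outside the Ex3aERKO range by more than that range in 432, against 57 to 1256 for the 14 other pairs of these 6 arrays, highest for Ex3aERKO 4 and Ex3bERKO 3, which share slide 4. Other values speak against exchanged samples: both arrays lay outside the Ex3aERKO range, by less than it for oocyte genes (-0.34 and 1.13 against -3.95 to -1.36) and Esr1 (-0.57 and -1.06 against -3.65 to -1.89), and by more than it for Defb8 (-4.51 and -4.93 against 0.31 to 1.38), Bpifb5 (3.00 and 3.52 against -0.57 to 0.37) and Srd5a1 (2.08 and 1.86 against -0.20 to 0.81), 3 genes chosen after their values were seen, and a mixed sample was not tested.

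Macrophage and lymphocyte genes were higher in Ex3abERKO. A lower share of the main cell type would raise the markers of all other types alike, and the endothelial change minus the macrophage change was -2.25 ± 0.18 (-0.41 against 1.84), which argues against it. Blood left in the tissue stays open, since the erythroid change minus the lymphocyte change was -1.65 ± 1.20 (0.35 against 2.00). The erythroid value rests on control 4: without it the change was 1.24 and the difference -0.86 ± 0.91. A biological effect, not tested, also stays open.

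Other arrays lay far from the remaining 3 of their group, given with the gap to the nearest array as a share of the group's range. In list means these were Ex3bERKO 2 for genes of both supporting cell types (0.872, at -0.03 against 0.42 to 0.48) and for oocyte genes (0.961, at -0.34 against 1.07 to 1.13). Control 2 stood apart for ovulation genes (0.870, at 0.64 against -0.27 to -0.15) and control 4 for erythroid genes (0.950, at 2.68 against -0.99 to -0.81). Ex3aERKO 4 stood apart for Wnt genes (0.857, at -0.75 against 0.10 to 0.24). In Ex3abERKO these were array 3 for ovulation genes (0.831, at 0.90 against 0.57 to 0.63), array 1 for oocyte genes (0.947, at -2.33 against -1.62 to -1.58) and cell cycle genes (0.862, at -0.46 against -1.26 to -1.15), and array 2 for estrogen response genes (0.873, at 1.10 against 0.70 to 0.75). Among single genes, Esr1 stood apart on Ex3aERKO 4 (0.834, at -3.65 against -2.18 to -1.89), Sox9 on Ex3bERKO 4 (0.840, at -2.83 against -1.84 to -1.66) and Cyp19a1 on control 2 (0.892, at 3.56 against 0.70 to 1.01).

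Over 186 named genes, 58 of 738 groups of arrays had such a gap, where 36.9 are expected by chance. The array apart was Ex3aERKO 4 in 17, Ex3abERKO 3 in 11, control 2 in 7, Ex3bERKO 2 in 6, control 4 and Ex3abERKO 1 in 3 each, Ex3aERKO 1, Ex3bERKO 3 and Ex3bERKO 4 in 2 each, and control 1, Ex3aERKO 2, Ex3bERKO 1, Ex3abERKO 2 and Ex3abERKO 4 in 1 each. In array statistics, Ex3bERKO 1 had 106 outlier spots against 65 to 66 (0.976), Ex3abERKO 4 had 19.6% of its signal in the top 100 probes against 18.4% to 18.6% (0.884), and Ex3bERKO 2 had a negative-control signal of 37.3 against 22.7 to 23.9 (0.920). Saturated spots numbered 7 on Ex3aERKO 3, 1 on Ex3bERKO 3 and 1 on Ex3abERKO 1 and 0 on the other arrays of each group (a share of 1).

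The interaction test called 896 genes and 12 lists. A positive value need not be a rise: Mmel1, Hsd17b7 and the luteal list lay below all controls on every knockout array. With an estimated correlation 0 of the 12 were called, and endothelium, stromal matrix and smooth muscle were lost with slide as a block. The list means were -1.13 (granulosa), -0.93 (both supporting cell types), -1.59 (theca and Leydig), 1.38 (luteal), 0.76 (Wnt), 0.95 (interferon), 1.00 (lymphocytes), 0.53 (endothelium), 0.63 (stromal matrix), 0.62 (smooth muscle), -1.13 (surface epithelium) and 2.56 (fat cells). Positive genes were Etos1 (7.05), Cfd (6.64), Mmel1 (6.46), Adipoq (6.39), Slc7a10 (6.10), Wnt10b (5.76), Cst9 (4.997), Rgcc (3.31), Hsd17b7 (3.101), Defb36 (3.06), Dmrt1 (2.76), Cyp26a1 (2.28), Fzd1 (2.24), Parm1 (2.18), Col1a1 (1.94), Aldh1a3 (1.92), Oasl2 (1.74), Sparc (1.27) and Egfl7 (0.86). Negative genes were Klk1b24 (-8.29), Hsd17b3 (-8.17), Cstdc2 (-7.87), Lcn2 (-7.03), Jak3 (-6.66), Insl3 (-6.63), Cyp17a1 (-5.74), Rhox5 (-4.22), Rasd1 (-2.85), Fshr (-2.83), Inhba (-2.78), Greb1 (-2.22), Gja1 (-2.18), Bmp2 (-2.01), Gata4 (-1.98), Nr5a1 (-1.75) and Aldh1a1 (-1.63). Dmrt1 was not called with a higher floor (adjusted p = 0.0523) and was well above background only in Ex3abERKO, so its value rests on substitute signals, as do in part those of Etos1, Slc7a10 and Klk1b24. Leaving out 1 array at a time ended the call for 13 of 16 arrays for Jak3, Insl3, Oasl2 and Col1a1, 12 for Egfl7 and Sparc, 11 for Parm1, 8 for Klk1b24 and Aldh1a3, 7 for Gja1 and Greb1, 5 for Etos1, 4 for Cfd, 3 for Adipoq, 2 for Bmp2 and 1 for Inhba. On Ex3bERKO 1 to 4, Insl3 was at 0.42, 5.65, 6.23 and -0.41. The Jak3 and Insl3 probes start at 70157730 and 70157953 of chromosome 8 and may not read separate genes.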

How the results depend on the processing

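The only alternative chosen after seeing the data leaves out the 3 arrays defined above. No call reversed. With slide as a block, the mean of some uncalled lists changed sign: oocytes (-0.04 to 0.18), macrophages (0.19 to -0.05) and erythroid genes (0.16 to -0.51) in the interaction. The test direction changed for erythroid genes in Ex3bERKO against control and immediate early genes in Ex3abERKO against Ex3aERKO. Trend and robust fits, a higher floor, quantile normalization, normexp, median scaling, the series table, the mean of a gene's probes, no filter on dim probes and slide as a random block moved no count by over 1.5 times and, where camera was run, ended no call of the granulosa and Sertoli lists in the 5 comparisons run. Signal limits the dim genes. The interaction has no value with only the groups compared, and camera was not run with slide as a random block. Where a result changed below, the cause was not tested, except that a minimum fold leaves fewer calls by construction.

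With array weights, 5594 genes were called in Ex3aERKO, 862 in Ex3bERKO and 9210 in Ex3abERKO against control, 6572 in Ex3abERKO against Ex3bERKO, 1612 in Ex3aERKO against Ex3bERKO and 1924 in the interaction. The granulosa list was lost in Ex3aERKO (adjusted p = 0.0552) and Ex3abERKO (0.0746) against control, and the Sertoli list in Ex3abERKO against Ex3aERKO (0.166). With probes well above background on all 16 arrays, the granulosa list was lost in Ex3aERKO (0.0502) and the Sertoli list in Ex3abERKO against Ex3aERKO (0.2005). Slide as a fixed block left 2191 genes in Ex3abERKO against Ex3bERKO. With only the groups compared, the counts were 89 for Ex3bERKO against control, 613 and 2488 for Ex3abERKO against Ex3aERKO and Ex3bERKO and 117 for Ex3aERKO against Ex3bERKO, and the granulosa list was lost in Ex3aERKO (0.0582). At least 2-fold were 3218 genes in Ex3abERKO against control, 1264 against Ex3aERKO and 2496 against Ex3bERKO.

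With an estimated correlation, camera lost the Sertoli list in Ex3aERKO (0.136), Ex3bERKO (0.139) and Ex3abERKO (0.106) against control and in Ex3abERKO against Ex3aERKO (0.403) and Ex3bERKO (0.305). It lost the granulosa list in Ex3aERKO (0.367) and Ex3abERKO (0.305) against control, in Ex3abERKO against Ex3aERKO (0.199) and Ex3bERKO (0.305), in Ex3aERKO against Ex3bERKO (0.336) and in the interaction (0.317). With fry, which tests a list against no change and not against the other genes, the granulosa list was lost in Ex3aERKO against control (0.212) and Ex3bERKO (0.259) and the Sertoli list in Ex3abERKO against Ex3aERKO (0.0842). Without the 3 arrays the counts were 551, 66 and 3336 for Ex3aERKO, Ex3bERKO and Ex3abERKO against control, 862 and 2512 for Ex3abERKO against Ex3aERKO and Ex3bERKO, 237 for Ex3aERKO against Ex3bERKO and 278 for the interaction.

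Leaving out 1 array gave 1157 to 2683 genes in Ex3aERKO, 110 to 381 in Ex3bERKO and 3977 to 6540 in Ex3abERKO against control, 1128 to 2331 and 2433 to 5226 in Ex3abERKO against Ex3aERKO and Ex3bERKO, 281 to 875 in Ex3aERKO against Ex3bERKO and 512 to 1363 in the interaction. The adjusted p of the granulosa list was 0.00518 to 0.242 in Ex3aERKO, 0.306 to 0.793 in Ex3bERKO and 0.00648 to 0.0833 in Ex3abERKO against control, and 7.23e-07 to 8.24e-05 and 0.00769 to 0.0840 in Ex3abERKO against Ex3aERKO and Ex3bERKO. That of the Sertoli list was 3.92e-06 to 6.62e-05, 2.46e-06 to 0.000174 and 1.29e-07 to 1.86e-05 in the same 3 comparisons with control, and 0.00336 to 0.0604 and 0.000661 to 0.0124 in the same 2 others.

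The labels give the groups the same replicate numbers, which do not pair the arrays: deviations of same-numbered arrays correlated at -0.295 to 0.443, over 0.1 in 7 of 24 pairs, and 4 of 16 arrays correlated best with an array of their own number. Slide does group the arrays: pairs on the same slide had a median r of 0.279, over 0.1 in 17 of 22, and 14 of 16 arrays correlated best with an array of their slide. The model and the regroupings leave slide out, so its blocked values are given beside the results. A replicate block gave 1829, 222 and 5334 genes in Ex3aERKO, Ex3bERKO and Ex3abERKO against control, 1616 and 3791 in Ex3abERKO against Ex3aERKO and Ex3bERKO, 489 in Ex3aERKO against Ex3bERKO and 720 in the interaction, and kept the calls of the granulosa and Sertoli lists in the 5 comparisons run.

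Of 418 results for named genes, a replicate block kept 393, slide as a fixed block 373 and leaving out the 3 arrays 295 on their side of the threshold, and none reversed.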

Other observations

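The tests of linked alleles and of other splits were chosen only after the results were seen.

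Cyp26a1, which breaks down retinoic acid, rose in Ex3abERKO against control by 3.28 ± 0.31 (9.70-fold, adjusted p = 2.23e-05) and Aldh1a3, which makes it, by 2.11 ± 0.33 (adjusted p = 0.000527), while Aldh1a1, another such enzyme, fell by 1.06 ± 0.25 (adjusted p = 0.00706). Bst2, an interferon-induced membrane protein, fell by 1.21 ± 0.22 (adjusted p = 0.00431) in Ex3aERKO, by 1.35 ± 0.22 (0.00850) in Ex3bERKO and by 1.44 ± 0.22 (0.000531) in Ex3abERKO. Without the 3 arrays its call was lost in Ex3aERKO (0.0720) and Ex3bERKO (0.0759), and in Ex3bERKO also with only the groups compared (0.0616).

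Results of the lists not described above follow. For called lists these are the genes higher and lower of those measured, the same adjusted over the list alone, the mean change (log2), the camera adjusted p and that with an estimated correlation, and for the others the mean change and the camera adjusted p, with the median and the direction of the test where signs differ. Calls that change when 1 array is left out end each paragraph, with the adjusted p without it.

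In Ex3aERKO against control, camera also called cell cycle (0 and 3 of 20, 0 and 16, -0.89, 6.72e-08, 0.308), interferon (0 and 1 of 16, 0 and 2, -0.61, 0.00372, 0.377), lymphocytes (0 and 0 of 16, 0 and 0, 0.70, 0.00118, 0.312) and surface epithelium (5 and 0 of 10, 9 and 0, 1.54, 1.78e-08, 0.136). No call was made for retinoic acid (0.22, 0.260), Wnt (-0.05, median -0.05, tested higher, 0.933), stromal matrix (-0.10, median -0.05, tested higher, 0.714) and smooth muscle (-0.01, median 0.08, tested higher, 0.603). Short of a call were oviduct (0.61, median -0.02, tested higher, 0.242), fat cells (-1.33, 0.170), erythroid cells (0.56, 0.198) and immediate early genes (-0.11, 0.606). Lost calls were interferon without Ex3aERKO 4 (0.0935). Gained calls were fat cells without control 4 (0.0364) or Ex3aERKO 2 (0.0152) and erythroid without control 4 (0.000237). The other way on 1 slide went interferon (0.75, -1.36, -0.30 and -1.52 on slides 1 to 4).

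For Ex3bERKO against control, camera also called genes of both supporting cell types (0 and 0 of 14, 1 and 0, 0.33, 0.00776, 0.214), interferon (0 and 1 of 16, 0 and 3, -0.69, 2.63e-07, 0.214), endothelium (0 and 0 of 13, 0 and 0, -0.22, 0.00619, 0.394, 0.163 with slide as a block) and surface epithelium (0 and 0 of 10, 1 and 0, 0.79, 0.000113, 0.385). Further called lists held immediate early genes (0 and 1 of 10, 0 and 2, -0.38, 0.00577, 0.116). The test left uncalled ovulation (0.21, 0.368), estrogen response (0.36, 0.427), retinoic acid (0.15, 0.427) and Wnt (-0.11, 0.236). Uncalled lists included cell cycle (0.06, 0.547), lymphocytes (0.30, 0.252), stromal matrix (0.04, 0.585) and smooth muscle (-0.26, 0.177). Camera made no call for oviduct (0.40, 0.427), fat cells (-0.48, 0.368) and erythroid cells (-0.36, 0.427, but 0.55, 0.31 and 1.03 within slides). Lost calls were endothelium without control 4, Ex3bERKO 1 or 3 (0.0545 to 0.0762). Gained calls were smooth muscle without control 3 (0.0338), lymphocytes without control 4 (0.0383) or Ex3bERKO 4 (0.0362), cell cycle without Ex3bERKO 2 (0.00312) and ovulation without Ex3bERKO 4 (0.0496). The other way on 1 slide went interferon (0.28) and immediate early genes (0.01).

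With Ex3abERKO set against control, camera also called ovulation (3 and 0 of 14, 3 and 0, 0.68, 0.0371, 0.305), Wnt (3 and 1 of 14, 5 and 1, 0.60, 0.0315, 0.305), stromal matrix (4 and 1 of 18, 5 and 1, 0.57, 0.00178, 0.305) and surface epithelium (5 and 0 of 10, 8 and 0, 1.20, 0.000255, 0.305). Called besides were oviduct (3 and 0 of 10, 3 and 0, 1.42, 0.00627, 0.305, a mean of 0.77 without Ex3abERKO 2, which was at 3.37 against 0.59, 0.65 and 1.07) and fat cells (3 and 0 of 11, 3 and 0, 0.75, 0.0456, 0.420). Remaining without significance were retinoic acid (0.46, 0.0724), interferon (-0.34, 0.246), smooth muscle (0.35, 0.121) and erythroid cells (0.35, 0.410). Lists not called were immediate early genes (-0.08, 0.607). Lost calls were ovulation without control 1, 3, 4 or Ex3abERKO 1 (0.0501 to 0.0685), fat cells without control 3, 4, Ex3abERKO 1 or 4 (0.0578 to 0.177) and Wnt without Ex3abERKO 1 (0.0685). Gained calls were interferon without control 1 (0.0164), erythroid without control 4 (0.0120) and smooth muscle without Ex3abERKO 3 (0.00758). The other way on 1 slide went fat cells (-1.07).

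Between Ex3abERKO and Ex3aERKO, camera also called luteal cells (1 and 4 of 12, 1 and 5, -0.48, 0.0445, 0.485), oocytes (0 and 0 of 23, 0 and 0, 0.70, 0.00322, 0.613), cholesterol synthesis (0 and 5 of 21, 0 and 7, -0.73, 1.98e-06, 0.358) and Wnt (3 and 0 of 14, 6 and 0, 0.65, 0.00509, 0.358). Called too were macrophages (2 and 0 of 20, 6 and 0, 0.75, 4.09e-06, 0.358), endothelium (0 and 0 of 13, 0 and 0, 0.30, 0.0160, 0.431, 0.146 with slide as a block), stromal matrix (3 and 0 of 18, 4 and 0, 0.67, 0.000444, 0.403) and oviduct (0 and 0 of 10, 0 and 0, 0.81, 0.0405, 0.439, 0.142 with slide as a block). A further call went to fat cells (4 and 0 of 11, 7 and 0, 2.08, 0.000155, 0.347). No call was made for ovulation (0.07, 0.628), estrogen response (-0.50, median 0.09, tested lower, 0.523), retinoic acid (0.24, 0.161) and cell cycle (-0.13, 0.628). Short of a call were interferon (0.27, 0.209), smooth muscle (0.36, 0.175), surface epithelium (-0.34, 0.246) and erythroid cells (-0.21, 0.741). The test left uncalled immediate early genes (0.03, 0.974). Lost calls were luteal cells without control 1, Ex3aERKO 1, 2, Ex3abERKO 2, 3 or 4 (0.0502 to 0.160), oviduct without Ex3aERKO 1, 3, 4 or Ex3abERKO 2 (0.0530 to 0.600), oocytes without Ex3aERKO 4 (0.399), Wnt without Ex3aERKO 4 (0.0887) and endothelium without Ex3abERKO 1 (0.0868). Gained calls were retinoic acid without Ex3aERKO 2 (0.0358), interferon without Ex3aERKO 2 (0.0191), surface epithelium without Ex3aERKO 4 (0.00542) and smooth muscle without Ex3abERKO 3 (0.00476). The other way on 1 slide went luteal cells (0.03), oocytes (-0.62), endothelium (-0.13), oviduct (-0.77) and fat cells (-0.05).

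Between Ex3abERKO and Ex3bERKO, camera also called genes of both supporting cell types (1 and 7 of 14, 1 and 7, -0.70, 0.0297, 0.305), cholesterol synthesis (0 and 5 of 21, 0 and 7, -0.64, 0.00215, 0.371), Wnt (3 and 0 of 14, 4 and 0, 0.71, 0.00215, 0.305) and cell cycle (0 and 13 of 20, 0 and 19, -1.08, 4.23e-07, 0.305). Called too were interferon (0 and 0 of 16, 0 and 0, 0.35, 0.0464, 0.501, 0.125 with slide as a block), lymphocytes (11 and 0 of 16, 12 and 0, 1.70, 1.07e-08, 0.271), stromal matrix (2 and 1 of 18, 2 and 1, 0.53, 0.00215, 0.320, 0.0511 with slide as a block) and smooth muscle (2 and 0 of 9, 2 and 0, 0.61, 0.0132, 0.338). A further call went to oviduct (1 and 0 of 10, 1 and 0, 1.02, 0.0132, 0.305, 0.0542 with slide as a block) and fat cells (2 and 0 of 11, 2 and 1, 1.23, 0.00538, 0.305). Below significance lay luteal cells (-0.36, 0.136), ovulation (0.47, 0.0619), estrogen response (0.45, 0.122) and retinoic acid (0.32, 0.0943). Without a call remained endothelium (-0.19, 0.217, 0.0235 with slide as a block), surface epithelium (0.41, 0.0943), erythroid cells (0.71, 0.136) and immediate early genes (0.29, 0.136). Lost calls were interferon without Ex3bERKO 3, 4, Ex3abERKO 1, 2 or 3 (0.0663 to 0.129), smooth muscle without Ex3bERKO 3, Ex3abERKO 1 or 2 (0.0612 to 0.0805), genes of both supporting cell types without Ex3abERKO 2 (0.0674) or Ex3abERKO 4 (0.0600) and oviduct without Ex3abERKO 2 (0.115). Gained calls were ovulation without control 2, Ex3aERKO 4, Ex3bERKO 2 or Ex3abERKO 4 (0.0160 to 0.0494), surface epithelium without Ex3bERKO 3 (0.0177) and luteal cells without Ex3abERKO 1 (0.0429). The other way on 1 slide went stromal matrix (-0.43), smooth muscle (-0.61) and fat cells (-0.04).

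Between Ex3aERKO and Ex3bERKO, camera also called cell cycle (0 and 2 of 20, 0 and 17, -0.95, 3.16e-12, 0.311), macrophages (1 and 0 of 20, 1 and 0, 0.54, 9.27e-05, 0.486), lymphocytes (0 and 0 of 16, 0 and 0, 0.41, 0.0120, 0.516) and endothelium (0 and 1 of 13, 0 and 7, -0.49, 1.61e-05, 0.311). Camera also called surface epithelium (0 and 0 of 10, 4 and 0, 0.74, 0.000275, 0.446) and erythroid cells (0 and 0 of 6, 0 and 0, 0.92, 0.0279, 0.516, 0.138 with slide as a block). The threshold was missed by genes of both supporting cell types (-0.09, median -0.02, tested higher, 0.857), theca and Leydig cells (0.21, median -0.21, tested lower, 0.857), luteal cells (0.12, 0.857) and ovulation (0.41, 0.0686). No shift was called in cholesterol synthesis (0.09, 0.203), retinoic acid (0.07, median -0.12, tested higher, 0.784), Wnt (0.06, 0.215) and interferon (0.08, 0.250). No call was made for stromal matrix (-0.14, median 0.01, tested lower, 0.982), smooth muscle (0.25, 0.0535), oviduct (0.21, 0.360) and fat cells (-0.85, 0.331). Short of a call were immediate early genes (0.26, 0.0535). Lost calls were lymphocytes without Ex3aERKO 3 (0.0560) or Ex3bERKO 4 (0.0940), erythroid without Ex3aERKO 3, Ex3bERKO 1 or 4 (0.0512 to 0.0813) and macrophages without Ex3bERKO 4 (0.0603). Gained calls were immediate early genes without control 1, 2, 3, Ex3aERKO 4, Ex3bERKO 2 or 3 (0.0157 to 0.0499), smooth muscle without control 3, Ex3aERKO 4, Ex3bERKO 1, 2, 4 or Ex3abERKO 3 (0.00298 to 0.0496), fat cells without Ex3aERKO 2 (0.0499) or Ex3bERKO 3 (0.0438), ovulation without Ex3aERKO 4 (0.0157) or Ex3bERKO 2 (0.0135), cholesterol synthesis without Ex3aERKO 4 (0.0101), Wnt without Ex3aERKO 4 (0.00202) and interferon without Ex3aERKO 4 (0.0101). The other way on 1 slide went macrophages (-0.11), surface epithelium (-0.98) and erythroid (-0.34).

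In the interaction, camera also called genes of both supporting cell types (0 and 3 of 14, 0 and 6, -0.93, 0.000243, 0.112), luteal cells (3 and 0 of 12, 4 and 1, 1.38, 0.00733, 0.388), Wnt (1 and 0 of 14, 2 and 0, 0.76, 0.00170, 0.317) and interferon (1 and 0 of 16, 3 and 0, 0.95, 0.000231, 0.317). To these add lymphocytes (0 and 0 of 16, 0 and 0, 1.00, 0.00148, 0.388), endothelium (1 and 0 of 13, 5 and 0, 0.53, 0.000861, 0.317, 0.0553 with slide as a block), stromal matrix (2 and 0 of 18, 3 and 0, 0.63, 0.0155, 0.546, 0.192 with slide as a block) and smooth muscle (0 and 0 of 9, 2 and 0, 0.62, 0.0432, 0.546, 0.0745 with slide as a block). Calls extended to surface epithelium (0 and 0 of 10, 0 and 0, -1.13, 0.00148, 0.388) and fat cells (2 and 0 of 11, 5 and 0, 2.56, 0.000520, 0.317). Not past the threshold were ovulation (-0.14, 0.792), oocytes (-0.04, median 0.01, tested lower, 0.877), estrogen response (-0.86, median 0.06, tested lower, 0.346) and cholesterol synthesis (0.34, 0.192). Below significance lay retinoic acid (0.10, 0.439), cell cycle (-0.19, 0.487), macrophages (0.19, 0.295) and oviduct (0.41, 0.295). Without a call remained erythroid cells (0.16, median -0.09, tested higher, 0.872) and immediate early genes (0.41, 0.0895). Lost calls were smooth muscle without control 1, 2, 4, Ex3aERKO 4, Ex3bERKO 3, Ex3abERKO 1 or 2 (0.0591 to 0.209), stromal matrix without Ex3aERKO 4, Ex3bERKO 4 or Ex3abERKO 1 (0.0619 to 0.143) and luteal cells without Ex3abERKO 1 (0.0634). Gained calls were cholesterol synthesis without control 2 (0.00274) or Ex3abERKO 4 (0.0245), macrophages without Ex3aERKO 3 (0.0383) or Ex3bERKO 2 (0.0171), oocytes without Ex3aERKO 4 (0.0276), cell cycle without Ex3bERKO 2 (0.0290) and immediate early genes without Ex3bERKO 3 (0.0471) or Ex3abERKO 3 (0.0480).

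Other ways of splitting the arrays into groups of the same sizes were fitted in the same model. As many genes as in the real split were called in 1 of 35 splits, the real one, for Ex3aERKO (1987 genes, highest other 1), Ex3bERKO (258, 4) and Ex3abERKO (5642, 4) against control, and Ex3abERKO against Ex3aERKO (1938, 2) and Ex3bERKO (4205, 130). That is the lowest share 35 splits allow, so chance is less likely but not excluded. For the interaction it was 1 of 100 drawn regroupings (896, highest other 102), which also break up pairwise differences and so cannot decide. For Ex3aERKO against Ex3bERKO it was 2 of 35, the other split calling 690 genes against 569 with Ex3aERKO 1, 2 and 3 and Ex3bERKO 2 on one side, so chance cannot be excluded. That other split puts all arrays of slides 1 and 2 on one side and those of slide 4 on the other, with slide 3 divided, so it follows the slides in part. With slide as a block the real split called 493 genes.

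Alleles linked to a targeted gene, carried over from the strain in which it was targeted, would raise the share of called genes near it. Within 10 Mb of Esr1, 5 of 76 genes were called in Ex3aERKO against control (Fisher's exact test, odds ratio 0.830, 95% interval 0.261 to 2.03, adjusted p = 1) and 18 of 76 in Ex3abERKO (1.09, 0.603 to 1.88, adjusted p = 1). Within 10 Mb of Esr2, 2 of 231 were called in Ex3bERKO (0.852, 0.102 to 3.15, adjusted p = 1) and 42 of 231 in Ex3abERKO (0.778, 0.542 to 1.09, adjusted p = 0.609). The intervals include both no excess and a moderate one, so the tests leave this open.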
